A study of Danio rerio with 6 samples.

How the data were processed

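RNA sequencing profiles were compared between hearts dissected from wild-type zebrafish embryos and hearts from embryos that had received a morpholino against tnnt2a. The gene encodes cardiac troponin T, a thin-filament protein of the heart muscle, and the mutant of this gene is known as silent heart because its heart does not beat. Per the labels, 6 libraries were made, 3 for each of the 2 groups, each from a pool of about 100 hearts taken at 54 hours post fertilisation (hpf). The morphant embryos had been injected with 1 ng of morpholino at the one-cell stage. Per the labels' protocols, the libraries were made from total RNA with a strand-specific kit. Whether strand was used when reads were assigned is not given in the sources used here.

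Per the submitters' processing notes, the tools were bcl2fastq, Trim Galore 0.4.1, cutadapt 1.9.1, FastQC 0.11.4, STAR 2.5.0c, Cufflinks 2.2.1 and Cuffdiff, and the genome build was GRCz10. The notes give these names without saying which step each served, and the gene annotation and the normalisation between libraries are not given in the sources used here. The authors' deposited table holds 1 FPKM value (fragments mapped to a transcript, scaled to its length and to the mapped fragments of the library) per feature and group, with the 3 replicates of a group merged by the authors into that value. The same deposited table holds a p-value and a q-value per feature. Its conditions are called control and sih. These were taken as the wild-type and morphant groups because sih abbreviates silent heart and the series has no other group. All folds below are morphant over wild type.

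No library has a column of its own in that table, so no standard deviation could be given beside any FPKM value and no test across replicates could be run here. The only such test is the authors' own, through the p-values and q-values of the table. Sequencing depth is unknown, and no counting interval or detection floor was computed. The test planned before the data were examined was the authors' own Cuffdiff q-value below 0.05, and it was used as planned. The q-values equalled Benjamini-Hochberg adjustment of the p-values over 19969 features within 1% for all 16383 listed features. The listed features are therefore those with the smallest p-values, up to 0.767, and 3586 tested features with larger p-values are not analysed here. The smallest p-value is 5e-05 and is shared by 577 features, so the q-values do not rank the strongest changes.

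The deposited columns of log2 fold change and test statistic hold spreadsheet error cells where a group is at 0, and folds were recomputed from the FPKM values. For all 15536 features above 0 in both groups the recomputed log2 fold equalled the deposited one within 0.001. A further 5 features are listed at 0 in morphants beside a finite deposited fold, and these cells contradict each other. A feature listed at 0 in 1 group (847 features) was given no fold value. Where a minimum fold was applied to all calls, called features listed at 0 were counted as past it, except with the pseudocount, which gives them a finite fold.

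The features carry assembly identifiers and GRCz10 coordinates but no gene names, and the gene tables used here are of another build. Gene names were therefore not assigned to any feature. The 30 gene lists fixed before the data were examined (flow-responsive, valve, sarcomere, blood and other sets) and the level of tnnt2a itself are not analysed here, and the rule for named genes, which required a gene symbol, named none. In its place the 2 called features with the largest rise and the 2 with the largest fall are named by identifier, among features with at least 1 FPKM in both groups. Coordinates are those of the authors' table, and a locus shared by several features is printed once for each of them.

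From the table the following were computed. Calls were counted by direction, abundance, chromosome and 1-Mb window. The share of called features on each of the 25 numbered chromosomes was set against all other features with a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over 50 tests. The fullest window was compared with 1000 shuffles of the calls over features. Features were divided into 4 equal groups by the width of their locus, and neighbouring calls were tested with 10000 shuffles of their directions. The shuffle tests are one-sided, counting shuffles with a value at least as large. Intervals for shares of features are 95% Wilson intervals, and differences of shares carry 95% bootstrap intervals from 1000 draws. Features are not independent replicates, so these tests describe how features are distributed in this table and not variation between embryos. The alternatives were other q-value limits, minimum FPKM values with recomputed adjustment, a minimum fold, recentred folds, a pseudocount of 1, leaving out features listed at 0 and leaving out shared loci. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

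The steps were tested on simulated data laid out on the listed 16383 features or part of them. Calls were shuffled, or p-values or folds were drawn at random. Adjustment recovered 200 of 200 planted features with 13 false calls. A chromosome given 40 extra calls was the only 1 of 25 to pass. With shuffled directions, 7 of 100 tables gave a neighbour test below 0.05. A planted difference of -19.7 percentage points between wide and narrow loci was estimated as -19.5. The planted effects were strong (the width difference observed was -8.69 points), so these runs check the steps and do not give their power at the sizes observed.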

Results

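Hearts of wild-type and tnnt2a morphant zebrafish embryos at 54 hpf were profiled by RNA sequencing, with 3 libraries per group. The comparison asks which transcripts of the embryonic heart differ in abundance after injection of a morpholino against tnnt2a. Neither the level of tnnt2a nor the beating of these hearts is analysed here. A morpholino dose is given for the morphant group alone, so effects of injection cannot be told apart from loss of tnnt2a. The authors' deposited table lists 16383 features on 25 numbered chromosomes and the mitochondrial genome, with 1 merged FPKM value per group. The median feature was at 6.11 FPKM in wild-type hearts and 6.43 FPKM in morphant hearts. The listed values summed to 760448 FPKM in wild-type and 786948 FPKM in morphant hearts. The 3 most abundant features of each group, of which 2 were the same, made up 19.4% of the wild-type sum and 19.5% of the morphant sum. Depth and replicate spread are unknown for these values, since the libraries were merged before deposition. The labels call the pools biological replicates, and the spread between them enters only through the authors' p-values and q-values.

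By the q-values of the authors' deposited table, 1021 features differed between the groups, which is 5.11% of the 19969 features the q-values were adjusted over. Of these, 545 were higher and 476 were lower in morphant hearts, so that 53.4% of the calls rose (95% Wilson interval 50.3% to 56.4%, which treats calls as independent). At a q-value below 0.01 the split was near even, with 357 rises and 346 falls (50.8% rising). Among the features called at a q-value below 0.05 and above 0 in both groups, 468 rose and 347 fell. The rises had a median of 2.73-fold (median log2 fold change 1.45, quartiles 1.04 and 1.95). The falls had a median of 2.14-fold (median log2 fold change -1.10, quartiles -1.57 and -0.83). In the same set, at least 2-fold changes were called for 365 rises and 195 falls (65.2% rising), at least 4-fold changes for 107 rises and 49 falls, and at least 8-fold changes for 19 rises and 15 falls. The split at 2-fold depended on the features left out and on the centre: with the called features listed at 0 counted as past the minimum it was 442 rises and 324 falls (57.7% rising), and with folds also recentred on the listed features it was 401 and 373 (51.8% rising). The smallest called change had a log2 fold change of 0.56 in size. At an unadjusted p-value below 0.05 in the authors' deposited table, 1605 features were higher and 1315 lower.

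**Figure D1:**
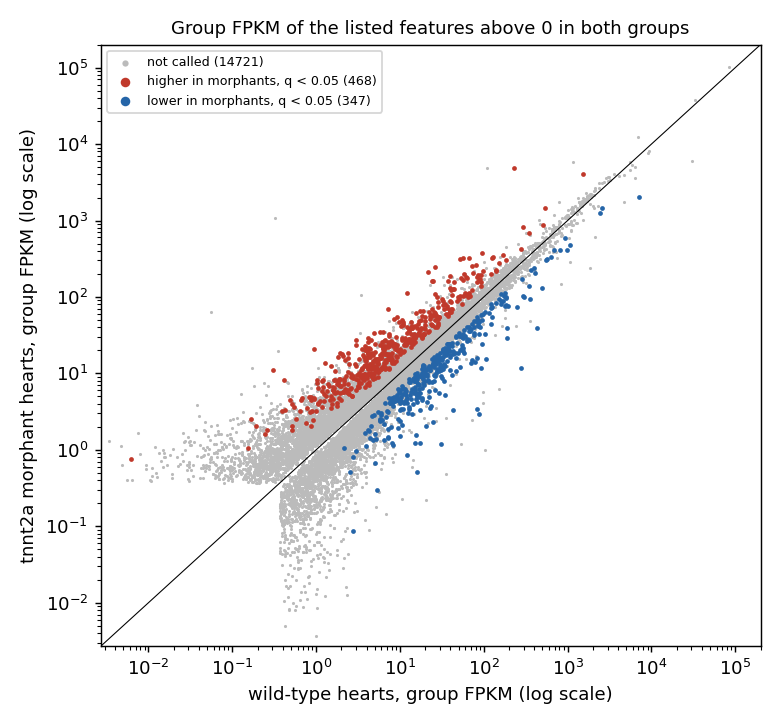
Group FPKM in wild-type hearts (horizontal, log scale) against tnnt2a morphant hearts (vertical, log scale), 1 point per listed feature above 0 in both groups, with the line of equality. The 468 features called higher and the 347 called lower lie on either side of the line, and several abundant features far from it were not called.

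The listed features as a whole were shifted towards higher values in morphants. Of 14078 features with at least 1 FPKM in the higher group and above 0 in both, 7513 were higher and 6565 lower, with a median log2 fold change of 0.12. The unlisted 3586 features have larger p-values. With all of them placed at no change the median was 0, which follows from their number and is no test of the shift. Since the features with the largest p-values are missing from the list, 0.12 is not an estimate of the centre of all tested features. Folds relative to this shift are given only as an alternative setting. On it the called rises had a median log2 fold change of 1.32 and the called falls -1.22. No call changed direction, because every called change was larger than the shift.

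Among called features with at least 1 FPKM in both groups, the largest rise was that of XLOC_028845, a 3828-bp locus on chromosome 8 (GRCz10, 16573953 to 16577781), which went from 232 FPKM in wild-type to 4808 FPKM in morphant hearts in the authors' deposited table. This is a 20.7-fold increase (log2 fold change 4.37, 4.25 relative to the shift, q = 0.00173), and it made this feature the most abundant of all called rises. The second was XLOC_005926, a locus of 139604 bp on chromosome 14 (15511490 to 15651094), which rose 10.4-fold from 1.29 to 13.5 FPKM (log2 fold change 3.39, q = 0.00173 in the authors' deposited table). The largest fall in this set was that of XLOC_014518, a 1042-bp locus on chromosome 21 (20347200 to 20348242). It went from 88.1 to 2.92 FPKM, a 30.2-fold decrease (log2 fold change -4.92, -5.04 relative to the shift, q = 0.00173 in the authors' deposited table). XLOC_016172, a 52262-bp locus on chromosome 22 (12616798 to 12669060), fell 25.7-fold from 31.0 to 1.21 FPKM (log2 fold change -4.68, q = 0.00173 in the authors' deposited table). None of these 4 features shared its coordinates with another listed feature. The table does not say which genes or which exons, introns or untranslated regions these loci hold.

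Calls included some of the most abundant features, at shares near those of the whole list. Of the 129 features of at least 1000 FPKM, 2.33% were called higher and 3.10% lower, against 3.33% and 2.91% of all listed features. The most abundant feature called lower, on chromosome 5, fell 3.48-fold from 7058 to 2028 FPKM (q = 0.00173 in the authors' deposited table). Next among the falls were a feature on chromosome 1, which went from 2581 to 1453 FPKM (q = 0.0124), and a feature on chromosome 2, which went from 2468 to 1249 FPKM (q = 0.0278, both in the authors' deposited table). Among the rises, a chromosome 17 feature went from 1521 to 4046 FPKM, 2.66-fold, and a chromosome 2 feature from 537 to 1455 FPKM, 2.71-fold (q = 0.00173 for both in the authors' deposited table). Of the 967 features with at least 100 FPKM in the higher group, 62 were called higher and 51 lower.

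Large differences in abundant features were not always called. In the band of at least 100 FPKM, 109 features above 0 in both groups differed at least 2-fold, and 47 of these were not called. Of the 33 that differed at least 4-fold, 16 were not called, 8 in each direction. The third most abundant feature of the table by the higher of its 2 values, on chromosome 3 (40384248 to 40387946), stood at 30465 FPKM in wild-type and 6024 FPKM in morphant hearts, 5.06-fold lower, with q = 0.415 in the authors' deposited table. A chromosome 21 feature stood at 108 FPKM in wild-type and 4844 FPKM in morphant hearts, 45.0-fold higher, with q = 0.814 in the authors' deposited table. A chromosome 11 feature stood at 1150 and 5781 FPKM, with q = 0.831 in the authors' deposited table. Without values per library, neither the spread between replicates nor the reason for these q-values is known.

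From 1 to 1000 FPKM, the share of features called was higher in each band of higher abundance. Features between 1 and 5 FPKM in the higher group were called higher in 1.84% and lower in 1.32% of cases. Between 20 and 100 FPKM these shares were 4.97% and 4.45%, and between 100 and 1000 FPKM they were 7.04% and 5.61%. Of the 129 features of at least 1000 FPKM, 3 were called higher and 4 lower. Below 1 FPKM, 34 of 1919 features were called higher and 78 lower, of which 33 and 78 were features listed at 0 in the other group.

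Features listed at 0 made up part of the calls. In the authors' deposited table, 556 features were at 0 in morphants and 291 at 0 in wild type, and 206 of these 847 were called, 129 of them lower and 77 higher in morphants. Their median level in the other group was 0.95 FPKM, and 194 of the 206 carried the smallest p-value of 5e-05. The share called was 24.3% among features listed at 0 and 5.25% among the others. Among the others under 5 FPKM, closer in abundance to the called features at 0, it was 1.01%. A feature at 2833 FPKM in 1 group was listed at 0 in the other and was not called (q = 0.534 in the authors' deposited table). A value of 0 here is therefore reported as listed at 0 and not as absence of the transcript.

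Calls were spread over all 25 numbered chromosomes. The share called higher ranged from 2.17% on chromosome 23 to 4.94% on chromosome 10, against 3.33% of all listed features. The share called lower ranged from 1.56% on chromosome 19 to 4.42% on chromosome 13, against 2.91% of all. None of the 50 two-sided Fisher's exact tests passed 0.05 after Benjamini-Hochberg adjustment (smallest adjusted p = 0.525), and 4 were below 0.05 unadjusted: chromosomes 9 and 10 for rises, and 13 and 19 for falls. The fullest 1-Mb window for rises was 32 to 33 Mb of chromosome 3, with 5 of 37 features higher and none lower. In 344 of 1000 shuffles of the calls a window was at least as full (permutation p = 0.345). For falls it was the first megabase of chromosome 9, with 4 of 36 features lower and 1 higher (permutation p = 0.827). The single listed mitochondrial feature (positions 6108 to 6423) stood at 44.0 FPKM in wild-type and 58.4 FPKM in morphant hearts and did not pass (q = 0.727 in the authors' deposited table).

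**Figure D2:**
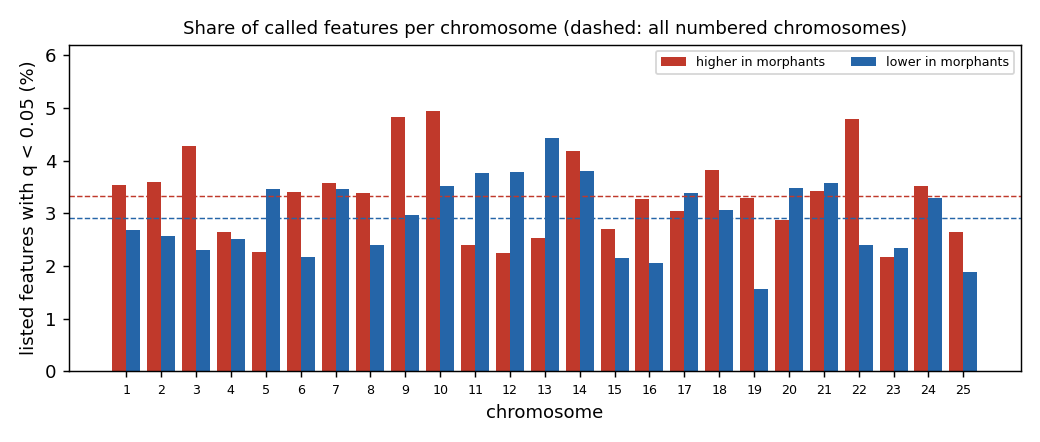
Percentage of listed features called higher (red) or lower (blue) in morphant hearts on each numbered chromosome, with dashed lines at the share over all of them. Shares called higher range from 2.17% to 4.94% and shares called lower from 1.56% to 4.42%.

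The direction of change differed with the width of the locus. Among features with at least 1 FPKM and above 0 in both groups, the loci were divided by width into 4 equal groups. The narrowest group (up to 9046 bp) had 146 calls higher and 61 lower in morphants, so that 70.5% of its calls rose. In the widest group (above 53478 bp) 88 were higher and 119 lower, so that 42.5% rose. The split differed between these groups of loci (two-sided Fisher's exact test, p = 1.27e-08, odds ratio 3.24). Over all features of this set, called or not, 58.3% of the narrowest group (95% Wilson interval 56.6% to 59.9%) and 49.6% of the widest (47.9% to 51.2%) were higher in morphants. This is a difference of -8.69 percentage points (95% bootstrap interval -10.9 to -6.16). Feature by feature the trend with width was weak (Spearman rho -0.05 across 14078 features). Median abundance was similar, at 10.4 FPKM for the narrowest and 9.40 FPKM for the widest group.

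**Figure D3:**
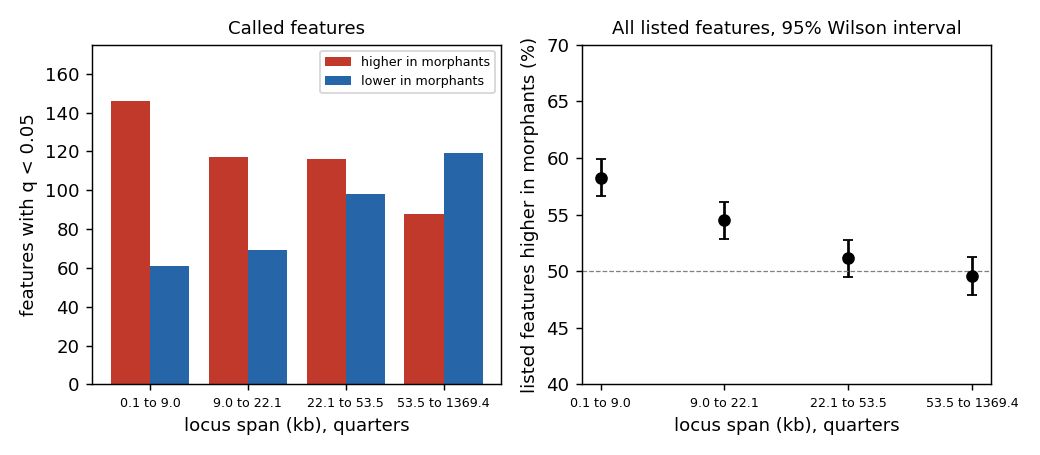
Left, number of features called higher (red) or lower (blue) in morphant hearts in 4 equal groups of features by locus width (kb, ranges on the axis). Right, percentage of the features of each group, called or not, that were higher in morphants, with 95% Wilson intervals and a dashed line at 50%. Both panels hold features with at least 1 FPKM and above 0 in both groups. Calls higher outnumber calls lower in the 3 narrower groups and are outnumbered in the widest.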

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

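The 545 rises and 476 falls stayed within 1.5 times under most of the settings run. Outside this, a q-value below 0.01 left 357 rises (and 346 falls), and a log2(FPKM + 1) change of at least 1 left 223 falls (and 370 rises). That setting applies a minimum fold and a pseudocount together, and the pseudocount also drops called features listed at 0 whose other value is below 1 FPKM (33 rises and 78 falls), which the minimum fold alone keeps. Of the calls, 53.4% rose in the main count, 50.8% at a q-value below 0.01, 57.7% with the minimum fold alone and 62.4% with both. Recentred folds of at least 1 gave 401 rises and 373 falls (51.8% rising), against 442 and 324 uncentred. Both counts include called features listed at 0, and without these, a combination added after the data were seen, they were 324 and 244 recentred and 365 and 195 uncentred, all but the 365 also outside 1.5 times. Alternatives added after the data were seen gave 468 rises and 347 falls without features listed at 0. Another, keeping features that shared coordinates with no other listed feature, gave 511 and 448. A minimum of 1 FPKM with recomputed adjustment gave 550 and 437 over the listed features, and 505 and 389 when the unlisted ones were added back. For the 4 named features, recentring by 0.12 and a pseudocount of 1 could not reverse folds of this size, so these 2 settings do not test their direction; the pseudocount lowered the rise of XLOC_005926 to a log2 fold change of 2.66. No paired analysis was possible because the deposited values merge the 3 replicates of each group. For the same reason leaving out each replicate, count-based tests and splits of the samples were not run. The alternatives for gene lists and for tnnt2a were not run because the features carry no gene names. Depth is unknown, so no limit of detection was set.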

Other observations

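Features on shared loci were called less often. Of 2374 features that shared their locus coordinates with another listed feature, 62 (2.61%) were called. Of the other 14009 features, 959 were called (6.85%, two-sided Fisher's exact test, p = 4.23e-18, odds ratio 0.36). Some of these 14009 may share a locus with a feature that is not listed. The difference remained among features of at least 20 FPKM, at 5.77% against 10.7% (Fisher's exact test, p = 5.17e-05). None of the 182 features on the 16 loci that held 8 or more features was called, against 6.30% of the rest (Fisher's exact test, p = 1.59e-05). The locus with the most, on chromosome 22 (1484667 to 2854042), held 35 features. Of the 935 shared loci, 61 held a call and only 1 held more than 1. Whether calls on a shared locus go the same way can therefore not be judged.

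The 3 patterns that follow were noticed in these data and tested on them. The tests of the first pattern, the alternative distances of the second and the counts on shared loci above were chosen after related results had been seen. The tests of the first pattern were recast from medians to shares because the list leaves out the features with the largest p-values, whose folds are unknown. Shares carry the same limit, since the directions of those features are unknown too. The first pattern is the lower share of rises on wide loci. Low abundance as its whole cause is argued against by a difference of -13.3 percentage points (95% interval -17.5 to -9.23) among features of at least 20 FPKM. Coordinates shared with another listed feature are argued against by -11.0 points among the features that had none. Loci shared with unlisted features could not be seen. Among features that were not called the difference was -7.45 points, so it was not confined to the calls. Calls were few in each width group, so this value largely follows from the overall difference and is no separate test. Locus width is not transcript length. RNA integrity, unspliced RNA, the mix of cell types, the injection and the knockdown itself remain open explanations that were not tested. A biological origin is therefore only a hypothesis.

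The second pattern is that neighbouring calls may move together. Of 121 neighbouring pairs of called features with different coordinates and starts less than 100 kb apart, 78 (64.5%) changed in the same direction, against 50.2% in 10000 shuffles (one-sided permutation p = 0.0006), with 63.9% at 50 kb and 62.0% at 200 kb. Features listed at 0 are argued against as the cause by 75.3% of 77 pairs without them (one-sided permutation p = 0.0001, the smallest the shuffles can give), and the trend with width by shuffling only among calls in the same of 4 groups by locus width (one-sided permutation p = 0.0013). A single gene split into adjacent features stays open. Of the 73 pairs with at least 10 kb between them, 61.6% changed in the same direction (one-sided permutation p = 0.0327). That p-value is below 0.05, the limit set beforehand for arguing against this explanation. However, the 95% Wilson interval of 50.2% to 71.9%, which treats pairs as independent, reaches the chance value of 50.2%, so the explanation is kept. Reads shared between tandem gene copies, a difference in genetic background between clutches and shared regulation remain open and were not tested.

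The third pattern is the set of features listed at 0 in 1 group. Reads assigned to an overlapping feature are a candidate explanation for part of it. At 5 FPKM or more, 61 of 109 such features (56.0%) shared their locus coordinates, against 13.2% of the others (odds ratio 8.38, 95% interval 5.72 to 12.3). Below 5 FPKM 23.6% did, against 14.8% (odds ratio 1.78, 1.48 to 2.14). Most of the weak features at 0 therefore shared coordinates with no other listed feature, though an unlisted one may overlap them. Low depth and loss of the transcript in 1 group stay open for these, since no counts per library were analysed here.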
